A study of Mus musculus with 6 samples.

How the data were processed

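RNA sequencing was done on osteoblasts from the calvaria of newborn mice, WT or KO for NDR1 (gene Stk38), after osteogenic differentiation, with 3 libraries per genotype. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates were separate animals, litters or cultures, nor the sex or strain of the mice or the design of the KO allele.

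The deposited table held 29018 genes with Ensembl identifiers, coordinates, annotation columns for GO and KEGG, and both count and FPKM columns for each library. The count columns, per the file headers and their whole-number values, were reads or fragments assigned to each gene by the authors, and the method of counting was not given in the sources used here. The FPKM columns were computed by the authors and deposited as FPKM, which are scaled to transcript length and to the total of each library. Between a pair of libraries, the ratio of count to FPKM differed by nearly the same factor for all genes. The submitters' processing notes named cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, with no parameters. The notes listed a human genome build although all identifiers were of mouse, and 502 of 27342 shared identifiers (1.84%) had the coordinates of GENCODE release M21, so the build of the coordinates was not settled.

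Total counts per library were 74962582, 61461870 and 76159034 for KO and 66308530, 66902151 and 68395991 for WT. Between replicates of a group the variance of a gene was 5.94 to 6.96 times counting noise at the median, and between groups 17.6 to 19.0 times, so the spread between libraries rather than depth set the precision for most genes. edgeR estimated a common biological coefficient of variation of 12.6%. Intervals and floors cover counting error and the spread between these libraries only.

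Tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. The plan assumed that only FPKM would be present and named edgeR as the test if counts were present, so the edgeR branch applied and the FPKM test became an alternative. Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, no covariate, two-sided) in R 4.3.3 with limma 3.58.1 and DESeq2 1.42.0. The filter kept 18221 genes, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were the absolute log2 change over the square root of F. A fold against a group without counts was computed against a floor of 3 counts over that group and is a lower bound. Stk38 was also tested by an exact permutation test on log2(FPKM + 1).

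There were 33 gene lists for bone, the NDR1 pathway, autophagy, PI3K-AKT signalling, other cell types and RNA quality, and 32 had at least 3 tested genes. Of the listed symbols, 26 were not in the table. Lists were tested with limma's camera at a preset correlation of 0.01, which called 12 lists, with camera and an estimated correlation, which called none, and with fry, which called 25, each with Benjamini-Hochberg adjustment over the lists. Annotation terms with 10 to 500 tested genes were tested with a one-sided Fisher's exact test, 4155 in all, against the 14982 tested genes that carried any term. Fisher's test treats genes as independent and takes no account of genes that move together. The direction of each list's test is that of camera.

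Named genes were Stk38 and Stk38l, then for each direction the 10 genes of largest log2 change among those called, with the 3 KO values on one side of the 3 WT values and a symbol that is not a predicted gene. For each list they were up to 4 members of lowest p and fixed core members (Runx2, Sp7, Alpl and Bglap, Becn1, Map1lc3b, Sqstm1 and Atg5, and Akt1, Pik3ca and Foxo1), and 1 further core member is not reported here. Genes named outside this rule were chosen after their values were seen. They are the members of annotation terms, Atg2b, Acp5, Cdh19, Plvap, Mx1, Gbp2, Ifi27l2a, Ifit1, Rnps1 and most genes of the closing section.

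Alternatives fixed before the data were examined were limma on log2(FPKM + 1) with a mean FPKM of at least 1, the same with a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median centring, quantile normalization, robust fitting, array weights or a replicate block, DESeq2, edgeR without a count filter or with a replicate block, minimum folds of 1.5 and 2, and leaving out each library. Alternatives added after seeing the data were edgeR with robust dispersion, with library totals without TMM, with the size factors of DESeq2, and without X and Y genes. The pipeline was tested on simulated data with 200 changed genes, where edgeR recovered 87% of genes changed 2-fold and 70% of those changed 1.5-fold with 7.65% false calls, DESeq2 92% and 76% with 13.8%, and limma on FPKM 80% and 55% with 4.93%. The planted list was called there, and 0 of 20 random lists, which held no changed gene. Changed genes were taken only from those with a mean count of at least 50, so recovery at lower counts was not tested. Genes were drawn independently in that simulation, so it does not test lists whose members move together.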

Results

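Gene expression was measured by RNA sequencing in osteoblasts, the cells that build bone, grown from the calvaria (skull vault) of newborn mice and taken through osteogenic differentiation. The cells were wild type (WT) or carried a knockout (KO) of NDR1, a serine/threonine kinase of the NDR/LATS family encoded by Stk38. There were 6 libraries, 3 of each genotype. The deposited counts summed to 74962582, 61461870 and 76159034 in KO replicates 1 to 3 and to 66308530, 66902151 and 68395991 in WT replicates 1 to 3. The single comparison, KO against WT, asked what loss of NDR1 does to the osteoblast transcriptome, and the series names PI3K-AKT signalling and Beclin-1-linked autophagy as the processes of interest. Levels are given as CPM, counts scaled to a common library size by TMM, ± SD with n = 3 per group, KO against WT, and changes as log2 KO over WT ± SE.

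KO cultures held less type I collagen and alkaline phosphatase mRNA, more osteopontin mRNA, and much less Mmp9 mRNA than WT cultures. Alpl, the phosphatase that frees phosphate for mineral, stood at 42.7 ± 3.42 against 97.0 ± 2.27 CPM (log2 change -1.19 ± 0.06). Col1a1 and Col1a2, the chains of type I collagen, changed by -0.46 ± 0.02 and -0.51 ± 0.02, while Spp1, which encodes the mineral-binding protein osteopontin, stood at 1729.7 ± 158 against 658 ± 52.1 CPM (1.39 ± 0.07). Mmp9, a gelatinase abundant in osteoclasts, stood at 3.72 ± 0.593 against 144 ± 7.76 CPM, a 38.5-fold lower level. These 5 genes passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p = 1.81e-07, 1.87e-07, 4.04e-08, 2.54e-07 and 6.56e-10 in that order. Col1a1 lost its call under quantile normalization of FPKM (log2 change 0), since it held the same rank in every library. Of 18 macrophage markers 16 rose (camera adjusted p = 7.85e-15, and adjusted p = 0.217 with an estimated correlation). Among them C1qc, a chain of complement C1q, stood at 27.0 ± 0.81 against 8.97 ± 1.45 CPM. The rise of Spp1 was of like size to that of the macrophage markers (median 1.27). Libraries of whole cultures do not show which cells gave it.

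The knocked-out gene itself fell but was still read. Stk38 (ENSMUSG00000024006, chromosome 17, 29189854 to 29226969 in the deposited coordinates, whose mouse genome build could not be settled) had 3843, 3004 and 4040 counts in the KO libraries and 4781, 5082 and 5331 in WT. Its level was 4.15 ± 0.165 FPKM in KO and 6.13 ± 0.264 FPKM in WT, and 50.2 ± 2.31 against 76.6 ± 3.24 CPM. The log2 change was -0.61 ± 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg, adjusted p = 8.10e-06), which left 65.6% of the WT level with a 95% interval of 61.4 to 70.0%. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Counts per gene pool all exons, and the part removed in the KO allele was not given in the sources used here. The paralog Stk38l, which encodes NDR2 (ENSMUSG00000001630, chromosome 6, 146626493 to 146680310), stood at 23.3 ± 2.63 against 22.7 ± 2.65 CPM, with a log2 change of 0.04 ± 0.10 that did not pass the test (edgeR, Benjamini-Hochberg adjusted p = 0.834).

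The genotypes differed widely. Of 18221 genes tested with edgeR's quasi-likelihood test, 2048 were higher and 2131 lower in KO at a Benjamini-Hochberg adjusted p under 0.05, and 470 and 366 of these changed at least 2-fold. The 3 KO values lay wholly above or below the 3 WT values for 4166 of the 4179 called genes and for 38.2% of all genes tested, where chance gives 10%. The split of calls depended on scaling, with 49.0% of calls higher after TMM, 64.4% higher in limma's test on log2(FPKM + 1) and 63.0% higher in edgeR on library totals without TMM. P-values measured only the spread between these libraries, which may be technical, since the labels did not say that replicates were separate animals or cultures. Xist, an RNA of female cells, varied little within a genotype (coefficient of variation 2.30% in KO and 5.59% in WT). The 4 Y-linked genes tested varied by 2.13% to 6.62%. Libraries of 1 pooled preparation per genotype would share such a sex mix, so the replicates may not be independent.

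Several genes were read in KO and absent or nearly absent in WT. Of those named here, Arhgap36 and Nexmif lie on the X chromosome. Prss41, a serine protease, and Treml4, an innate immune receptor, both on chromosome 17, were at least 69.7-fold and at least 19.9-fold higher, against a floor of 3 counts over the WT libraries, which held none. On the same floor Serpinb2, the plasminogen activator inhibitor type 2, was at least 16.2-fold and the zinc importer Slc39a4 at least 11.6-fold higher. Arhgap36, an inhibitor of protein kinase A, changed by 6.11 ± 0.70, the neuropeptide Vip by 5.62 ± 0.77 and the complement inhibitor C4bp by 4.36 ± 0.19 (9.98 ± 0.927 against 0.484 ± 0.116 CPM). Rnps1-ps, a processed copy of the splicing factor gene Rnps1, stood at 29.9 ± 1.28 against 0.816 ± 0.134 CPM, while Rnps1 fell (32.5 ± 0.914 against 82.8 ± 3.99 CPM). Reads that fit both the copy and its parent may be counted for either, so both values are uncertain. The neuronal gene Nexmif (4.64 ± 0.99) and the phosphodiesterase Pde2a (3.90 ± 0.84) completed the 10 largest increases, but without KO replicate 1 neither passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0516 and 0.0572, and up to 0.143 and 0.186 under other alternatives).

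The 10 largest decreases included genes of muscle and fat cells. Mybph, Myot and Klhl40, which encode sarcomere-associated proteins, were at least 44.7-fold, at least 21.4-fold and at least 15.6-fold lower, against a floor of 3 counts over the KO libraries, which held none. On that floor Cidec, a lipid droplet protein, was at least 29.1-fold and Pck1, which encodes phosphoenolpyruvate carboxykinase, at least 26.9-fold lower. The lipid droplet coat gene Plin1 stood at 0.0567 ± 0.0982 against 2.91 ± 0.548 CPM (-5.57 ± 0.75). Pkhd1, the fibrocystin gene, was at least 33.8-fold lower, the calpain Capn11 (chromosome 17) at least 39.6-fold, the vesicular zinc transporter Slc30a3 at least 30.2-fold and Ly6k at least 15.3-fold. Cidec, Myot and Pkhd1 lost their calls in limma's test on FPKM without a filter on low values (adjusted p = 0.0723, 0.0734 and 0.0739).

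**Figure D1:**
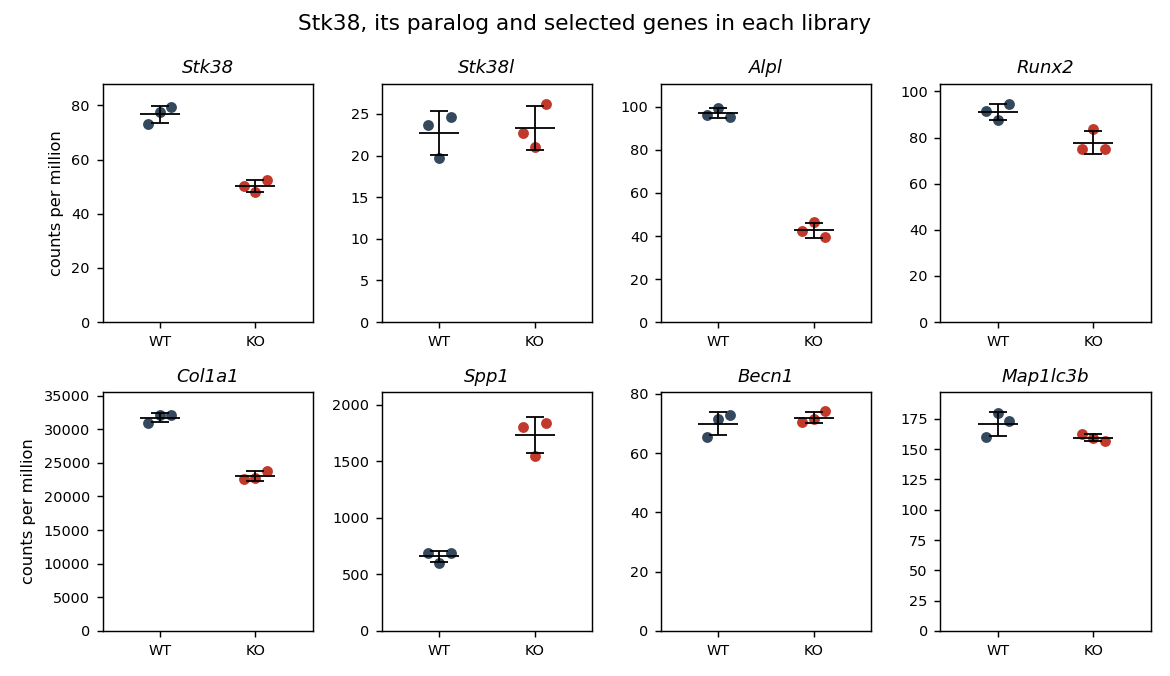
CPM (TMM-scaled) of 8 genes in each library, 1 point per library, with the mean and SD of the 3 WT and the 3 KO libraries. KO values of Stk38, Alpl and Col1a1 all lie below those of WT and those of Spp1 above, while the groups overlap for Stk38l and Becn1.

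Of 30 genes of bone matrix and mineralization, 20 fell and 4 rose in KO (21 and 5 adjusted over the list alone), with a median log2 change of -0.29. As a group the list was lower than other genes in camera with a preset correlation (Benjamini-Hochberg adjusted p = 2.36e-07), but adjusted p = 0.0674 with an estimated correlation. Besides Alpl, Col1a1, Col1a2 and Spp1, Bglap, an osteocalcin gene, was barely read (0.39 ± 0.182 against 0.732 ± 0.332 CPM) and its log2 change of -0.90 ± 0.50 did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.249). How reads that fit both Bglap and Bglap2, another member of the list, were counted was not given, so this level may be too low. Among 24 osteoblast regulators 8 fell and 4 rose (8 and 5 adjusted over the list alone, camera adjusted p = 0.307). Runx2, the master transcription factor of osteoblasts, stood at 77.8 ± 5.14 against 91.2 ± 3.44 CPM (-0.23 ± 0.05, adjusted p = 0.00756 in edgeR's quasi-likelihood test with Benjamini-Hochberg, but adjusted p = 0.0584 in limma's test on log2(FPKM + 1)). Over the 22 alternatives its adjusted p ran from 7.19e-05 to 0.130 in edgeR, limma and DESeq2. Sp7, which encodes osterix, was at 0.15 ± 0.07 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.201), though it did in limma on FPKM with a replicate block (log2 change 0.18, adjusted p = 0.0475). The homeobox gene Msx2 rose from 57.5 to 99.0 CPM and the Wnt co-receptors Lrp5 (-0.38 ± 0.04) and Lrp6 (-0.33 ± 0.03) fell. Of 10 osteocyte genes 5 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 0.0774, but adjusted p = 0.0440 without a count filter and 0.00126 with fry, which asks only whether members move one way on balance), with the mineralization protein Dmp1 at -1.18 ± 0.10 and the membrane protease Mmp14 at -0.38 ± 0.02.

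Most fibroblast matrix genes fell as well. Of 26 fibroblast matrix genes 20 fell and 2 rose (21 and 2 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 2.46e-14, and adjusted p = 0.0674 with an estimated correlation). Eln, the elastin gene, changed by -1.62 ± 0.05, the proteoglycan Dcn by -0.92 ± 0.03 and the secreted Wnt modulator Sfrp2 by -1.91 ± 0.06 (804 ± 86.7 against 3013 ± 121 CPM), whereas fibronectin (Fn1) rose by 0.75 ± 0.03. Of 16 suture and mesenchymal progenitor markers 7 fell and 4 rose (7 and 4 adjusted over the list alone, camera adjusted p = 0.109, but 0.00366 with fry). Among them were the matrix gene Dpt (-1.36 ± 0.06), the growth factor receptor Pdgfra (-0.61 ± 0.03) and the transcription factor Twist1 (-0.47 ± 0.04). Of 16 chondrocyte markers 7 fell and 2 rose (7 and 2 adjusted over the list alone). Matn1 was at -4.54 ± 0.22 and Col9a1 at -1.25 ± 0.04, but Col2a1 at 0.60 ± 0.04 and its regulator Sox9 at 0.52 ± 0.04. That list passed in camera (adjusted p = 0.038) but not with an estimated correlation (adjusted p = 0.476) or without WT replicate 3 (adjusted p = 0.0828). On FPKM it was not called with a mean of at least 5, median centring or quantile normalization (adjusted p = 0.362, 0.0890 and 0.0692).

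Most autophagy genes were not called at the mRNA level. Beclin-1 protein, AKT activity and autophagy itself were not measured in these libraries. Becn1, which encodes Beclin-1, stood at 72.0 ± 1.89 against 70.0 ± 4.0 CPM, with a log2 change of 0.04 ± 0.05 that did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.608). Of 42 autophagy genes 4 fell and 1 rose (4 and 1 adjusted over the list alone). Those that fell were the initiating kinases Ulk1 (-0.31 ± 0.04) and Ulk2 (-0.26 ± 0.05), the receptor Calcoco1 (-0.30 ± 0.03) and the lipid transfer gene Atg2b (-0.19 ± 0.05), and the protease Atg4a rose (0.23 ± 0.06). Ulk2 lost its call in limma on FPKM without a filter on low values (adjusted p = 0.0651). The list median was -0.04 (camera adjusted p = 0.204), although fry gave adjusted p = 0.0142. The cargo receptor Sqstm1 was at 0.00 ± 0.03, the conjugation gene Atg5 at -0.10 ± 0.06 and Map1lc3b, which encodes LC3B, at -0.10 ± 0.04, none of them called by edgeR, with Benjamini-Hochberg adjusted p = 0.971, 0.30 and 0.119. Without WT replicate 1, Map1lc3b passed in the same edgeR test (log2 change -0.15, adjusted p = 0.0158, the lowest of 22 alternatives that reached 0.603).

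Of 31 lysosome genes 10 rose and 1 fell (10 and 5 adjusted over the list alone), with a median of 0.02 and camera adjusted p = 0.109. The list passed as higher in limma on FPKM without a filter on low values (adjusted p = 0.00159), in edgeR without a count filter (adjusted p = 0.0437) or without TMM (adjusted p = 0.00882) and with fry (adjusted p = 0.0145). The proteases Ctsd (0.48 ± 0.02) and Ctsb (0.34 ± 0.03) and the acid lipase Lipa (0.30 ± 0.03) rose, and these genes are also abundant in macrophages, whose markers rose in the same libraries.

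Genes of the PI3K-AKT core changed in both directions. Of 35 members 10 fell and 8 rose (11 and 10 adjusted over the list alone). The median was -0.01, the mean 0.02 and the camera test pointed down without passing (adjusted p = 0.809). The catalytic subunit Pik3ca (-0.23 ± 0.04), the forkhead factor Foxo1 (-0.32 ± 0.07) and Tsc2, a brake on mTORC1 (-0.38 ± 0.03), fell. In limma's tests on FPKM, Foxo1 lost its call without a filter on low values and with a replicate block (adjusted p = 0.0947 and 0.0680), and Pik3ca with a replicate block (adjusted p = 0.0580). The adaptor Irs1 (0.29 ± 0.03), the mTORC2 subunit Rictor (0.56 ± 0.06) and the phosphatase Inpp5d (1.18 ± 0.11), known chiefly from blood cells, rose. Akt1 changed by -0.09 ± 0.02 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0164). Its call was lost without KO replicate 1, KO replicate 3 or WT replicate 3 (adjusted p = 0.0635, 0.0597 and 0.0645) and in limma's test on log2(FPKM + 1) (adjusted p = 0.226), within a range of 9.45e-04 to 0.295 over the 22 alternatives.

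Among 50 growth factors and receptors upstream of PI3K, 18 rose and 14 fell (19 and 17 adjusted over the list alone), with a median of -0.00, a mean of 0.05 and a camera test that pointed up without passing (adjusted p = 0.774, but 0.0145 with fry). The growth factor Igf2 fell 2.98-fold, at 589 ± 5.55 against 1755 ± 51.4 CPM (-1.58 ± 0.02), and Ntrk2, the receptor for BDNF, changed by -2.49 ± 0.08. The oncostatin M receptor Osmr (0.90 ± 0.03) and the hepatocyte growth factor Hgf (1.25 ± 0.06) rose. Of 18 targets of FOXO factors 8 fell and 4 rose (9 and 4 adjusted over the list alone, camera adjusted p = 0.171, but 0.00424 with fry). Gadd45a (-1.16 ± 0.09), Txnip (-0.64 ± 0.05) and Sesn1 (-0.50 ± 0.05) were lower and the cell cycle inhibitor Cdkn1a (0.77 ± 0.03) higher.

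**Figure D2:**
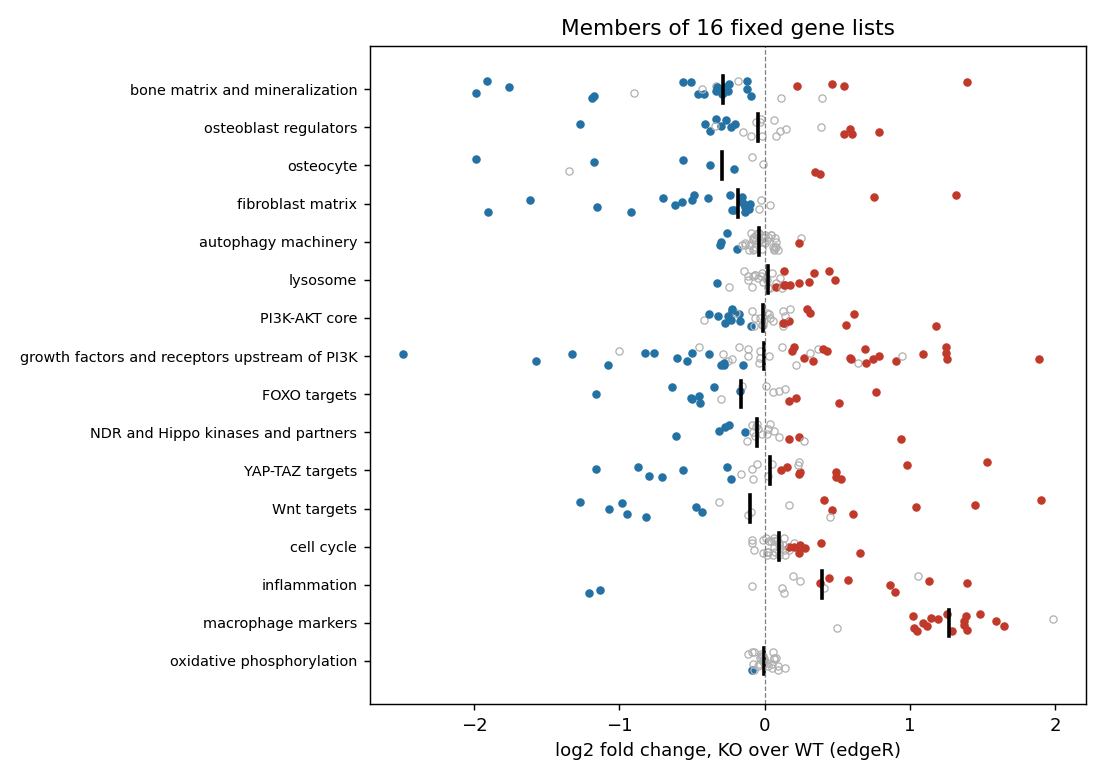
Log2 change, KO over WT, of each tested member of 16 gene lists, 1 point per gene, filled where called by edgeR (red higher, blue lower in KO) and open where not, with a black bar at the list median. Medians lie at -0.29 for bone matrix and mineralization, -0.04 for autophagy machinery, -0.01 for the PI3K-AKT core and 1.27 for macrophage markers.

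Other pathways around NDR1 and bone formation held genes that rose and genes that fell. Of 22 NDR and Hippo kinases and partners 5 fell and 3 rose (5 and 4 adjusted over the list alone, camera adjusted p = 0.328, but 0.00105 with fry). Stk38, the MST1 kinase gene Stk4 (-0.31 ± 0.05), Wwtr1, which encodes TAZ (-0.27 ± 0.04), and Tead2 (-0.24 ± 0.04) were lower. The wider KEGG Hippo pathway was enriched among lower genes (35 of 141, one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0114), with 24 higher (adjusted p = 0.37). Of 24 YAP-TAZ targets 9 rose and 7 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.832), Ccn2 standing at 0.98 ± 0.04 and Tgfb2 at -0.87 ± 0.03. Of 18 Wnt targets 6 rose and 7 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.805). Cyclin D1 (Ccnd1) was at 1.04 ± 0.02, Lgr5 at -1.07 ± 0.05 and Nkd1 at -0.98 ± 0.06. Of the KEGG Wnt pathway 43 of 151 genes were lower (20.9 by chance, adjusted p = 1.99e-04) and 22 higher (adjusted p = 0.693). Of 20 BMP and TGF-beta targets 7 rose and 4 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.234, but 0.00206 with fry). The BMP antagonists among them went opposite ways, Grem1 at 1.62 ± 0.08 and Nog at -1.38 ± 0.13. Of 14 osteoclast regulators made by osteoblasts 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.191, but 0.00126 with fry). Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, rose 3.74-fold, to 174 ± 10.3 against 46.5 ± 3.4 CPM, Sema3e changed by 1.51 ± 0.07 and Wnt16 by -1.24 ± 0.08. The KEGG osteoclast differentiation pathway was enriched among higher genes (39 of 121, 15.7 by chance, adjusted p = 1.43e-05), with 15 lower (adjusted p = 1). Besides Tnfrsf11b its largest increases were in myeloid genes such as Ncf4 and Fcgr1, beside higher macrophage markers.

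Among proliferation and stress genes more rose than fell. Of 35 cell cycle genes 8 rose and none fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.00213, and adjusted p = 0.27 with an estimated correlation). Cyclin E1 (Ccne1) was at 0.65 ± 0.07 and the ubiquitin-conjugating enzyme Ube2c at 0.39 ± 0.06. Of 24 hypoxia and glycolysis genes 11 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00524, and adjusted p = 0.192 with an estimated correlation). The angiogenic factor Vegfa was at 0.59 ± 0.06 and the glycolytic enzyme Pgam1 at 0.38 ± 0.03, against Pdk1 at -0.38 ± 0.06. Of 16 inflammation genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00517, and adjusted p = 0.192 with an estimated correlation), beside higher macrophage markers. That call was also lost in 7 of the 9 FPKM settings (adjusted p = 0.0723 on log2(FPKM + 1), and 0.0606 to 0.0738 over the 7). The collagenase Mmp13 was at 0.89 ± 0.06 and the adhesion gene Icam1 at 0.44 ± 0.04, but complement C3 at -1.21 ± 0.07. Of 22 ER stress and amino acid response genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.177), with Sesn2 at 0.57 ± 0.05 and Ddit3 at 0.43 ± 0.09. This list passed in limma on FPKM without a filter on low values (adjusted p = 0.0124), in edgeR without TMM (adjusted p = 0.0422) and with fry (adjusted p = 0.0107).

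Mitochondrial transcripts, read here as a sign of RNA quality, changed by small amounts. Of 28 oxidative phosphorylation genes 1 fell and none rose (0 and 0 adjusted over the list alone, camera adjusted p = 0.896). That 1 was Atp5f1a (-0.09 ± 0.02), whose edgeR call was lost without KO replicate 1, KO replicate 2 or WT replicate 2 (Benjamini-Hochberg adjusted p = 0.0905, 0.0530 and 0.0665), and in limma's test on log2(FPKM + 1) (adjusted p = 0.266), reaching 0.39 over the 22 alternatives. Of 15 mitochondrially encoded transcripts 2 fell and none rose (2 and 0 adjusted over the list alone), with mt-Co1 at -0.08 ± 0.02 and mt-Rnr1 at -0.20 ± 0.06. The call of mt-Co1 was lost in all 9 FPKM settings (log2 change -0.03 and adjusted p = 0.465 on log2(FPKM + 1), and adjusted p of at least 0.052 over the 9) and without TMM (adjusted p = 0.267). That list passed in camera (adjusted p = 0.0239) but not with an estimated correlation (adjusted p = 0.476) or without KO replicate 3 or WT replicate 3 (adjusted p = 0.127 and 0.0828). Nor did it pass in any FPKM setting (adjusted p = 0.122 to 0.727), without TMM (adjusted p = 0.2) or with fry (adjusted p = 0.13). The ribosomal RNA mt-Rnr1 lost its edgeR call without KO replicate 1, KO replicate 3, WT replicate 1 or WT replicate 2 (Benjamini-Hochberg adjusted p = 0.116, 0.0786, 0.0863 and 0.106), and also in 6 FPKM settings (adjusted p = 0.0621 to 0.187), without a count filter (adjusted p = 0.0668) and without TMM (adjusted p = 0.0892). Of 18 immediate early and heat shock genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.40, but 0.0377 with fry). Junb was at 0.58 ± 0.07, Dusp1 at 0.44 ± 0.07, Fosl1 at 1.17 ± 0.19 and Egr2 at -0.47 ± 0.14. Egr2 was called by edgeR with all libraries and without WT replicate 3 but not without any of the other 5 (Benjamini-Hochberg adjusted p = 0.0542 to 0.106), nor in 5 other settings (adjusted p = 0.0537 to 0.0942).

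The interferon response was uneven between libraries. Of 27 genes 2 rose, Mx1 (1.12 ± 0.34) and Gbp2 (0.59 ± 0.19), and 1 fell, Ifi27l2a (-1.08 ± 0.34), with 0 and 0 adjusted over the list alone (camera adjusted p = 0.134). Ifit1, an antiviral effector, stood at 66.4, 55.1 and 175 CPM of the library total in KO replicates 1 to 3 and at 52.1, 34.2 and 61.9 in WT. The list passed in camera without KO replicate 1 (median 0.57, adjusted p = 0.0266) or KO replicate 2 (0.65, adjusted p = 0.00262), and with a replicate block in edgeR (0.34, adjusted p = 0.0222). Those calls used the preset correlation. With all libraries and an estimated correlation, which was 0.867, camera gave adjusted p = 0.802. With 1 library left out, Mx1 and Gbp2 kept their calls only without KO replicate 2, and Ifi27l2a only without KO replicate 3. Without each other library in turn, edgeR's quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.0628 to 0.165, 0.0646 to 0.148 and 0.0709 to 0.156 in that order. The log2 changes of Mx1 and Gbp2 shrank to 0.71 and 0.27 without KO replicate 3. Over all alternatives the adjusted p of Mx1, Gbp2 and Ifi27l2a reached 0.179, 0.247 and 0.253.

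Markers of other cell types moved in both directions. Of 18 macrophage markers 16 rose and none fell (18 and 0 adjusted over the list alone), with a median of 1.27 (camera adjusted p = 7.85e-15, and adjusted p = 0.217 with an estimated correlation). The complement gene C1qb stood at 30.1 ± 1.51 against 10.8 ± 1.57 CPM, the scavenger receptor Cd68 at 34.8 ± 2.57 against 13.3 ± 1.8 CPM and the mannose receptor Mrc1 at 94.7 ± 11.7 against 39.8 ± 4.38 CPM. Of 9 osteoclast markers 3 fell and 1 rose (3 and 1 adjusted over the list alone). Those that fell were Mmp9, the cathepsin Ctsk (-0.45 ± 0.03) and the integrin Itgb3 (-0.80 ± 0.07). Tnfrsf11a, which encodes RANK, rose (1.05 ± 0.27), a call lost without KO replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0655). The osteoclast phosphatase Acp5 was at 0.07 ± 0.08 and not called, and the list had a median of 0.07, a mean of -0.67 and a downward camera test that did not pass (adjusted p = 0.109). It passed as lower in limma on log2(FPKM + 1) (median -0.40, adjusted p = 0.0134), in all 8 FPKM settings that filter low values (median -0.40 to -0.51, adjusted p = 0.00349 to 0.0281) and with fry (adjusted p = 1.66e-04).

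Several fat and skeletal muscle markers fell. Of 10 adipocyte markers 7 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -2.27 (camera adjusted p = 6.57e-04, and adjusted p = 0.26 with an estimated correlation). That median rests in part on genes near the floor. In the 8 FPKM settings that filter low values the list was not called, with a median of -0.15 to -0.20 (adjusted p = 0.0900 to 0.232, and 0.0964 on log2(FPKM + 1)). The fatty acid carrier Fabp4 stood at 0.607 ± 0.215 against 6.84 ± 1.89 CPM, adiponectin (Adipoq) at 0.0782 ± 0.0689 against 1.76 ± 0.419 CPM and lipoprotein lipase (Lpl) at 122 ± 3.98 against 251 ± 5.48 CPM. Of 12 skeletal muscle markers 4 fell and none rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.00647, and adjusted p = 0.27 with an estimated correlation). The myosin Myh8 stood at 1.01 ± 0.489 against 21.5 ± 2.52 CPM. Mylpf was at -2.56 ± 0.28, and Myl1 (-3.76 ± 0.83) and Myh3 (-1.41 ± 0.33) lost their edgeR calls without WT replicate 1 and WT replicate 2, at Benjamini-Hochberg adjusted p = 0.0626 and 0.0520, and in limma on FPKM without a filter on low values, at adjusted p = 0.123 and 0.0538.

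Of 9 endothelial markers 4 fell and none rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.094). The list passed in limma on FPKM without a filter on low values (adjusted p = 0.0150), in edgeR without a count filter (adjusted p = 0.0437) or without TMM (adjusted p = 0.0363) and with fry (adjusted p = 0.00116). Its members that fell were Tek (-0.82 ± 0.13), Ramp2 (-1.21 ± 0.19), Cdh5 (-1.63 ± 0.34) and Plvap (-0.93 ± 0.27). Plvap was called by edgeR with all libraries and without WT replicate 3 but not without any of the other 5 (Benjamini-Hochberg adjusted p = 0.0512 to 0.110), nor in limma on FPKM without a filter on low values or edgeR without a count filter (adjusted p = 0.0574 and 0.0565). Of 12 smooth muscle and pericyte markers 6 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.182, but 0.0282 with fry). The pericyte gene Rgs5 was at 2.08 ± 0.15 and smooth muscle actin (Acta2) at -0.20 ± 0.03, a call lost in limma on FPKM without a filter on low values (adjusted p = 0.117). Of 8 Schwann and neural markers 4 rose and none fell (4 and 1 adjusted over the list alone). They were the neuronal genes Stmn2 (36.8 ± 3.57 against 11.8 ± 1.25 CPM) and Tubb3 (1.64 ± 0.12) and the glial genes S100b (0.84 ± 0.09) and Cdh19 (0.68 ± 0.17). The call of Cdh19 was lost without KO replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0606). This list passed in camera (adjusted p = 0.0414) but not with an estimated correlation (adjusted p = 0.27) or without KO replicate 1, 2 or 3 or WT replicate 3 (adjusted p = 0.11, 0.0663, 0.11 and 0.0828). It was also lost in 6 FPKM settings (adjusted p = 0.0723 to 0.241), without a count filter (median -0.05, adjusted p = 0.109) and without TMM (adjusted p = 0.0710). Genes of red cells and granulocytes were too low to test.

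Transcripts that depend on sex chromosomes differed between the genotypes. Xist, the RNA that silences 1 X chromosome in female cells, stood at 388 ± 7.11 against 106 ± 5.99 CPM. The Y-linked genes Ddx3y (-0.73 ± 0.05), Kdm5d (-0.83 ± 0.06), Uty (-0.83 ± 0.07) and Eif2s3y (-0.65 ± 0.06) fell, and both Xist and all 4 Y-linked genes were read in every library. The 5 genes, 1 higher and 4 lower (1 and 4 adjusted over the list alone), passed in camera (adjusted p = 0.023) but not with an estimated correlation (adjusted p = 0.26). On FPKM they were not called as a list with a mean of at least 5, median centring or quantile normalization (adjusted p = 0.387, 0.0890 and 0.0615). With X and Y genes left out, an alternative chosen after seeing the data, 1955 genes were higher and 2045 lower in KO. Leaving them out removes no effect of sex on genes of other chromosomes. Sex-linked levels differed with genotype in every library, so effects of the sex mix cannot be told apart from those of NDR1 loss.

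**Figure D3:**
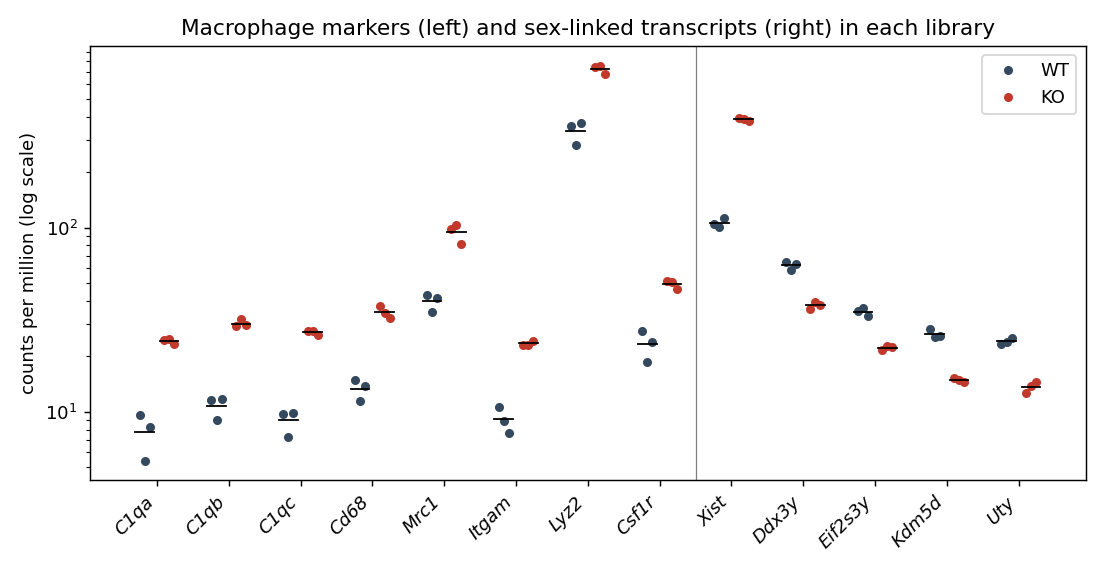
CPM (TMM-scaled, log axis) of 8 macrophage markers and 5 sex-linked transcripts in each library, 1 point per library, with a bar at the mean of the 3 WT and the 3 KO libraries. All 3 KO values lie above all 3 WT values for the macrophage markers and Xist, and below them for the 4 Y-linked genes.

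Annotation terms carried by the deposited table were tested with one-sided Fisher's exact tests. With Benjamini-Hochberg adjustment over 4155 terms, 266 were enriched among genes higher in KO and 215 among genes lower in KO. These tests treat genes as independent, so their p-values can be too small where genes move together, and they do not measure the spread between libraries. Of the gene lists, none passed camera with an estimated correlation. The members named here were chosen after their values were seen. Genes lower in KO included 117 of 254 of the collagen-containing extracellular matrix (35.1 by chance, adjusted p = 1.88e-32), and 60 of the 254 were higher (32.9 by chance, adjusted p = 3.00e-04). Ossification genes were lower for 41 of 97 (13.4 by chance, adjusted p = 2.65e-09), and bone mineralization genes for 19 of 49 (6.77 by chance, adjusted p = 0.00106). Another 20 of the 97 and 12 of the 49 were higher (12.6 and 6.34 by chance, adjusted p = 0.158 and 0.150). Genes annotated with Wnt receptor activity were lower for 13 of 16 (2.21 by chance, adjusted p = 5.88e-07), with the basement membrane gene Nid1 (-0.71 ± 0.02), the Frizzled receptor gene Fzd4 (-0.66 ± 0.04), Lrp5 and Lrp6. The KEGG PI3K-Akt pathway, which counts ligands, receptors and matrix proteins, was enriched both ways, with 66 of 301 genes higher (39.0 by chance, adjusted p = 8.38e-04) and 63 lower (41.6 by chance, adjusted p = 0.0128). The KEGG autophagy pathway was enriched neither way, with 17 of 157 genes higher and 20 lower (adjusted p = 1 for both). The KEGG lysosome pathway was higher for 39 of 120 (15.5 by chance, adjusted p = 1.26e-05), with Ctsd beside the macrophage genes Slc11a1 (1.31 ± 0.09), Ctss (1.56 ± 0.12) and Cd68, and 11 were lower (adjusted p = 1), among them Ctsk and Atp6v0c (-0.72 ± 0.03), whose value is uncertain beside a processed copy that rose.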

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

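Minimum folds, DESeq2, the FPKM tests, fry and the left-out libraries were fixed beforehand, while robust edgeR, library totals without TMM, the size factors of DESeq2 and removal of X and Y genes were chosen after seeing the data. Of the 194 named genes 179 were called, 165 kept the call without each library in turn, 14 lost it without at least 1, 24 lost it under any setting and none changed direction while called. Most named genes were chosen for low p or large change, so these counts do not stand for all called genes. The Stk38 decrease passed under every setting run. All genes called both by edgeR and under another setting had the same sign. Leaving out 1 library gave 1588 to 1731 genes higher and 1712 to 1893 lower, from fewer libraries. Of all 4179 called genes, 3175 to 3361 were still called with 1 library left out. The FPKM settings called 1928 to 3104 of them, the fewest with mean FPKM of at least 5. Most FPKM settings tested fewer genes than edgeR, so some of those calls were lost to the filter. DESeq2 called 2230 higher and 2325 lower, edgeR without a count filter 1788 and 1680, and edgeR with a replicate block 1912 and 1976. Deviations of replicates of equal number were nearly uncorrelated (r = -0.04, -0.03 and -0.01). That does not exclude a shared litter, day or batch, on which the labels are silent. Ifit1, for example, was lowest in replicate 2 and highest in replicate 3 of both genotypes. Fewer genes were lower in limma on log2(FPKM + 1), 1267, and with pseudocount 0.1, 1254, no filter on low values, 1246, mean FPKM of at least 5, 897, robust fitting, 1274, array weights, 1288, and the FPKM replicate block, 1095. The median change of all genes was 0.04 on FPKM and 0.00 after TMM, and median centring of FPKM gave 1487 higher and 1815 lower. At least 2-fold changes numbered 470 higher and 366 lower, by construction. Terms enriched among higher genes numbered 164 on log2(FPKM + 1), 163 with pseudocount 0.1, 33 with mean FPKM of at least 5, 159 median centred, 161 quantile normalized, 152 robust, 137 with array weights, 420 without a count filter and 177 at a 1.5-fold minimum, and among lower genes 95 with mean FPKM of at least 5, 135 quantile normalized, 335 without a count filter and 77 at a 1.5-fold minimum. Called lists numbered 6 with mean FPKM of at least 5, 0 with an estimated correlation and 25 with fry. With an estimated correlation bone matrix (median -0.29, adjusted p = 0.0674) and macrophage markers (median 1.27, adjusted p = 0.217) lost their calls, and with fry 14 lists gained one (adjusted p = 1.66e-04 to 0.0377), autophagy among them (median -0.041, adjusted p = 0.0142). Except where stated, the cause was not tested. Over all lists and settings 657 verdicts were unchanged, 59 were lost and 34 gained, and over named genes 3770, 127 and 16. Quantile normalization gave Col1a1 and mt-Co1 a change of 0, since each held the same rank in every library.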

Other observations

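Of the tests of explanations in this part, those of the parents of the retrocopies, the markers of other cell types, the genes below the share of Stk38, the KO allele and the other splits of the libraries were chosen after their results were seen. Genes of the p53 pathway and of cholesterol synthesis were enriched among genes higher in KO, in tests that treat genes as independent. Members named here were chosen after their values were seen. Of 72 tested genes of the KEGG p53 pathway 33 were higher (9.32 by chance, one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.64e-08). They included the cell cycle inhibitor Cdkn1a (437 ± 14.1 against 257 ± 4.35 CPM), Ccng1 (542 ± 1.73 against 289 ± 7.3 CPM), the cyclin D genes Ccnd1 and Ccnd2 (1.04 ± 0.02 and 0.88 ± 0.02 on the log2 scale) and Perp (1.99 ± 0.10). Another 8 were lower (9.95 by chance, adjusted p = 1), among them Igfbp3 (-0.80 ± 0.03), Gadd45a (-1.16 ± 0.09), Sesn1 (-0.50 ± 0.05), Tsc2 (-0.38 ± 0.03) and Igf1 (-0.39 ± 0.03). Mdm2, a p53 target that restrains p53, changed by 0.51 ± 0.04, while Trp53 itself was at -0.03 ± 0.03 and not called by edgeR (Benjamini-Hochberg adjusted p = 0.533). Of 29 cholesterol biosynthesis genes 17 were higher (3.75 by chance, adjusted p = 6.92e-06), among them Idi1 (0.50 ± 0.04) and Msmo1 (0.52 ± 0.05).

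Some abundant genes outside the lists fell several-fold, among them Septin6 (-4.75 ± 0.10), the secretogranin Scg2 (-4.16 ± 0.14), Tspan8 (-3.39 ± 0.10) and the matrix genes Hmcn1 (-2.56 ± 0.06) and Fndc1 (-2.33 ± 0.05). Tenm1 (2.34 ± 0.10) and Wdfy1 (2.02 ± 0.07) rose several-fold. Septin6 and Tenm1 lie on the X chromosome. Of 12 Hox genes tested, which mark position along the body, 5 fell, including Hoxa2 (-1.56 ± 0.17) and Hoxd8 (-1.13 ± 0.12), and Hoxb9 rose (1.46 ± 0.36). Among X-linked genes that escape silencing, Eif2s3x (0.41 ± 0.03), Kdm6a (0.25 ± 0.06) and Kdm5c (0.17 ± 0.03) rose beside Xist, and Ddx3x was at 0.05 ± 0.03 and not called, though it passed in 6 settings, among them limma on log2(FPKM + 1) (0.10, adjusted p = 0.0367) and edgeR without TMM (0.10, adjusted p = 0.0311). In CPM of the library total, Gapdh stood at 46.4 in KO replicate 2 and at 11.1 to 12.6 in the other libraries, and Isg15, an interferon-induced gene, at 143.9 in KO replicate 3 and at 27.2 to 62.6 in the others. How reads that fit several genes were counted was not given, and the Gapdh values may reflect it rather than expression. Gapdh is also a member of the hypoxia and glycolysis list.

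Processed copies of 4 genes on chromosome 17, where Stk38 lies, rose in KO, namely Rnps1-ps (5.19 ± 0.11), Atp6v0c-ps2 (2.99 ± 0.06), Rps2-ps6 (2.67 ± 0.06) and Hmga1b (2.42 ± 0.07). All 4 parents fell, Rnps1 (-1.35 ± 0.05), Atp6v0c (-0.72 ± 0.03), Rps2 (-0.32 ± 0.03) and Hmga1 (-0.54 ± 0.09), which is part of the pattern itself, so copies made more in KO with parents counted apart from them stay open. Sequence variants of another strain around Stk38, carried along with the KO allele, may send reads of the parents to the copies. Of 14 other processed pseudogenes at least 2-fold higher in KO with a parent found, 11 (78.6%) had it within 20 Mb of Stk38, against 3.74% of 1017 that were not called. These are not independent, since 10 of the 11 are copies of Rps2, a gene of the pattern itself, and by distinct parents the share is 2 of 5, so the variants remain a hypothesis, and no strain variant was read.

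The summed level of copy and parent differed between KO and WT by -0.42 for Rnps1, 0.05 for Atp6v0c, -0.19 for Rps2 and 0.49 for Hmga1 on the log2 scale. Of genes within 10 Mb of Stk38, 25.3% were called, against 22.9% elsewhere (Fisher's exact test, p = 0.246).

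Macrophage markers were higher in KO with a median log2 change of 1.27. For a further list of myeloid genes a prediction was written before the list was tested. Some of its genes, Dock2 and Coro1a among them, also stood among the higher genes of enriched annotation terms. The list may therefore not be blind to these data. It had a median of 1.18 (quartiles 0.83 and 1.37), with all 30 tested genes above 0 and 23 of them called higher. This is consistent with more macrophages in the KO cultures, or with macrophages richer in RNA. A smaller share of the main cell type in KO would raise markers of every other type alike. The 45 markers of 6 other types with at least 1 CPM in both groups did not rise alike. Their median was -0.046 and upper quartile 0.23, below the macrophage lower quartile of 1.10. Markers that the main cell type also makes need not rise in that case and were not set apart, so this argues against it only in part. Whether the difference arose from the genotype, the sex mix of the pups or the dissection stays open, since the labels give nothing that separates them.

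Stk38 kept 65.6% of its WT level in KO. RNA or cells of WT cultures in the KO libraries are argued against by 437 called genes whose 95% interval lay wholly below that share, which an admixture of that size forbids. Reads shared with other genes are argued against by the 0.745% of 50-base windows of Stk38 transcripts (90 of 12085) that occurred in other genes, with 0 in Stk38l. A KO allele that still makes part of the transcript cannot be told apart from other causes, because counts per gene do not resolve exons. No biological explanation beyond the allele was tested.

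The split of the libraries into KO and WT called 4179 genes, and the highest of the other splits called 1. As large a count came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.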
